A study of Mus musculus with 6 samples.

How the data were processed

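RNA recovered with anti-HA beads, meant to hold ribosome-bound RNA of microglia, was compared with whole-tissue RNA. The tissue was hippocampus of female C57BL/6 mice that carried Tmem119-Cre and the RiboTag allele. RiboTag is a form of the ribosomal protein gene Rpl22 that gains an HA epitope tag after Cre recombination, so that anti-HA beads can pull down ribosomes, and the RNA bound to them, from cells that express Cre. Per the labels, 3 libraries were made from RNA precipitated with anti-HA magnetic beads (IP) and 3 from RNA taken without antibody (input). Group membership was taken from the sample titles. Replicates were numbered in accession order, and each IP library was paired with the input library that shares its title code. The labels name the sex, strain and genotype of the mice. They do not say in words that each title code is a separate animal, so p-values measure the spread between the coded specimens.

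Per the labels' protocols, RNA was isolated on columns, and stranded libraries were made after mRNA enrichment. Per the submitters' processing notes, bcl2fastq 2.17, FastQC and Trimmomatic were used and reads were placed on mm10. The aligner, the counting program, its strand setting and the annotation release are not given in the sources used here. The authors deposited a table of whole-number read counts per gene, not normalized, with 39017 gene identifiers and 1 column per library. All 6 columns were used. Of the identifiers, 37607 were named by the GENCODE M21 annotation and 1410 had no symbol there. Those without a symbol held 0.419% to 0.475% of the counts of a library and were kept in library sizes and tests. A further 12 identifiers shared a symbol with another identifier, and 17550 had no count in any library. Every row had a gene identifier. Coordinates are from GENCODE M21 on GRCm38, the assembly also called mm10. Because the strand setting is not known, values of overlapping and antisense genes are uncertain, as are those of genes with near-identical copies.

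Library totals ran from 18448897 to 20422140 counts in input and from 10757351 to 18558497 in IP. A count of 0 allows up to 3 counts per library, which corresponds to 0.147 to 0.279 CPM, the count scaled to a fixed library total, at these totals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No 2 libraries of a group agreed within sampling noise: the chi-square per degree of freedom between libraries of a group was 25.3 to 49.5.

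The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) of IP against input on the deposited counts, with TMM factors, the filterByExpr filter (minimum count 10), robust dispersion and no block. P-values were adjusted by the Benjamini-Hochberg method and called below 0.05. Log2 folds are IP over input, fitted with a prior count of 0.125, and SE is the standard error of the log2 fold from the F statistic. CPM values are scaled by the TMM factors and given as mean ± SD over 3 libraries. A fold against a group with no count was computed at a floor of 3 counts over the group. With 1 to 3 counts in a group, the ratio of CPM is given with its 95% counting interval.

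Fixed lists of cell type markers, pathways and RNA classes, 36 in all, were written before the data were examined. Of these, 33 had at least 3 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the 33 lists. Camera was repeated with an estimated correlation, and fry was run as a test of each list by itself. For each pair, a list's fold was the median over members of the log2 difference of CPM + 0.5. The named genes were fixed by rule: the 10 higher and 10 lower genes with the largest fitted fold among called genes with average log2 CPM of at least 3 and the same direction in all 3 pairs, without unnamed models; the 2 most abundant tested members of each list; and Tmem119, Rpl22, Kdm6a, Xist and the Y-linked genes. Some genes that the rule takes are not reported here. Other genes named in the text are list members or were chosen after their values were seen.

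Pairing was taken from the shared title code, since an input is a sample of the lysate that is precipitated. It was checked on 11181 genes with average log2 CPM of at least 3. The correlation of deviations from the group means within a code was 0.05, 0.23 and 0.16, against -0.18 to 0.02 between codes, and each library correlated best with its own code. The first of these values is low.

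The test was run on data simulated for the 16196 genes that pass the filter, with the real dispersions and library sizes. Means were pooled over IP and input, and 200 genes were changed by 2-fold or 4-fold. Of the simulated genes, 15565 passed the filter again and were tested. The test recovered 12.4% of 2-fold and 57.3% of 4-fold changes. It made 72 calls, of which 5 were false, and 1 of 20 unchanged lists had a camera p below 0.05. The real data had 7722 calls and many larger folds, so these rates need not hold for them. Simulated genes were also drawn independently, so members of the unchanged lists were not correlated. Estimated correlations within real lists reached 0.73, for mitochondrially encoded genes. The count of unchanged lists below 0.05 therefore does not bear on false calls of correlated lists.

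Alternatives fixed before the data were examined were other scaling factors, no filter or a stricter one, DESeq2 1.42.0, limma-voom, the title code as a block, leaving out each library and each pair, thinning to the smallest total, a 2-fold minimum, other prior counts and pseudocounts, and the other list tests. A correction for transcript length, with and without the block, was added after the data were seen. Transcript length was the longest annotated transcript of a gene, which need not be the expressed one, and 98.4% of tested genes had one. Relations of fold and length across genes used 100000 permutations and intervals from 2000 bootstrap draws. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used for these steps and the plots.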

Results

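RNA was sequenced from hippocampus of female mice whose Tmem119-expressing cells, the microglia, carried HA-tagged ribosomes. There were 3 input libraries, of whole-tissue RNA, and 3 IP libraries, of RNA recovered with anti-HA beads. Input libraries 1, 2 and 3 held 20422140, 18448897 and 19190085 counts. IP libraries 1, 2 and 3 held 18558497, 12958727 and 10757351. At least 1 count was found for 18182 to 18789 genes in input and for 15153 to 16780 in IP. Mitochondrially encoded genes took 6.63% to 10.3% of the counts in input and 0.360% to 1.31% in IP. The series title concerns deletion of Kdm6a in microglia. The labels of these 6 libraries name neither a deletion of Kdm6a nor a disease model, so the comparison they allow is IP against input. It gives which RNAs were recovered with the anti-HA beads relative to the tissue. No library of beads without tagged ribosomes was analysed here, so RNA on tagged ribosomes was not told apart from background.

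Microglial RNAs were far higher in IP than in input. Tmem119, the gene whose promoter drives Cre (ENSMUSG00000054675, chromosome 5, 113793729 to 113800516, minus strand, GRCm38), rose from 26.2 ± 2.40 CPM in input to 2238 ± 162 CPM in IP (SD, n = 3 each). Its log2 fold was 6.41 with an SE of 0.18 (edgeR adjusted p = 9.6e-08), and it was higher in IP in all 3 pairs. Over 16196 tested genes, 3853 were higher and 3869 lower in IP (edgeR quasi-likelihood test, Benjamini-Hochberg). More than 4-fold differences were seen for 1745 of the higher and 1708 of the lower genes. The direction held in all 3 pairs for 3843 of the higher and 3867 of the lower genes. These genes were called on the same libraries, so this agreement largely follows from their selection. Fewer genes were called with a pair left out: 2802, 2930 and 3395 higher genes and 2526, 2917 and 3543 lower genes without pairs 1, 2 and 3. With a 2-fold minimum in the test, 2176 genes were higher and 2020 lower.

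All 14 genes of the microglial signature were higher in IP, with a median log2 fold of 5.82 (camera adjusted p = 4.5e-41, and adjusted p = 0.018 with an estimated correlation). The per-pair median was 5.82 ± 0.12 on the log2 scale (SD, n = 3 pairs). Selplg, which encodes the P-selectin ligand, rose from 88.1 ± 13.4 to 6614 ± 1095 CPM. All 24 pan-myeloid genes were also higher, with a median of 5.95 (camera adjusted p = 1.8e-59, and adjusted p = 0.018 with an estimated correlation). Among them, Csf1r, the receptor for colony stimulating factor that microglia need to survive, reached 9028 ± 1449 CPM from 111 ± 19.7 CPM. Laptm5, a lysosomal membrane protein of blood cell lineages, reached 5843 ± 937 CPM from 70.6 ± 9.85 CPM. All 13 myeloid transcription factors were higher, with a median of 5.27 (camera adjusted p = 1.2e-28, and adjusted p = 0.018 with an estimated correlation). Sall1, which maintains microglial identity, had a log2 fold of 5.27 (SE 0.20). Counts of called genes adjusted over the list alone equalled those over all genes tested for these 3 lists and for every other list below, except where both are given.

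**Figure D1:**
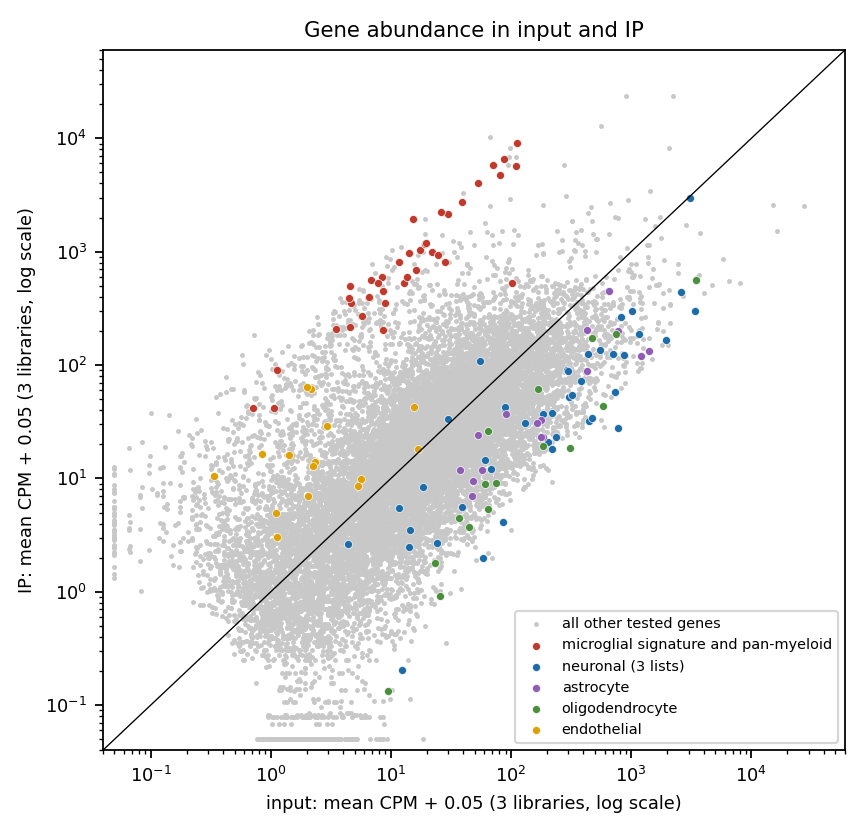
Mean CPM of each tested gene in 3 input libraries (x axis) and 3 IP libraries (y axis), both on log scales with 0.05 CPM added, with the line of equal abundance. Microglial and pan-myeloid genes (red) lie above the line with median log2 folds of 5.82 and 5.95, and oligodendrocyte markers (green) lie below it with a median of -3.17.

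The 10 higher genes with the largest fitted folds under the naming rule were Myo1g, Dusp27, Naip5, Gp9, Abcc3, Cysltr1, Gpr183, Itgb3, H2-Oa and Gpr179. Outside the rule, fitted log2 folds reached 10.5 in the disease-associated microglia list and 10.2 in the antigen presentation list. For 3 of the 10 the input held 1 to 3 counts. Myo1g, an unconventional myosin of blood cells, had 1 count in input and 792 in IP, a ratio of 1163 with a counting interval of 208 to 46010. Dusp27 had 3 and 1326 counts, a ratio of 649 (222 to 3152), and Naip5, an inflammasome sensor of flagellin, had 2 and 867 counts, a ratio of 637 (176 to 5267). Their input counts were in library 1 alone for Myo1g, library 3 alone for Dusp27 and library 2 alone for Naip5, and without that library the input was at 0. The ratio of Myo1g was 764 without pair 2. That of Dusp27 was 418 without input library 1, 1051 without IP library 1 and 333 without pair 2, and its IP libraries 1, 2 and 3 were at 8.16, 52.4 and 52.5 CPM. That of Naip5 was 410 without input library 1, 386 without pair 1 and 404 without pair 3. Naip5 has close paralogs, so its value is uncertain. Abcc3, a membrane transporter, rose from 0.675 ± 0.625 to 186 ± 37.3 CPM. Gpr183, an oxysterol receptor, rose from 0.370 ± 0.273 to 78.3 ± 11.8 CPM, and Itgb3, an integrin subunit, from 0.536 ± 0.366 to 103 ± 20.1 CPM. Cysltr1, a leukotriene receptor, had only 5 counts in input and 790 in IP, with a log2 fold of 7.72 (SE 0.58). H2-Oa had 0, 0 and 11 counts in input libraries 1, 2 and 3, and its log2 fold of 7.44 (SE 0.97) was 6.61 without pair 2 and 6.84 without input library 1. Without input library 3 or pair 3 its input was at 0. Gpr179 had a log2 fold of 7.39 (SE 0.95), which was 6.31 without IP library 2, 6.78 without input library 1 and 8.23 without input library 2. That of Abcc3, 8.08, was 7.35 without pair 2, 8.77 without input library 3 and 8.78 without pair 3, and that of Gpr183, 7.71, was 8.42 without input library 2 and 8.30 without pair 2. With limma-voom the log2 fold was 8.84 for H2-Oa and 9.20 for Abcc3, with a prior count of 2 it was 6.57 for Cysltr1 and 6.78 for H2-Oa, and on thinned libraries it was 8.46 for Gpr183 and 8.38 for Itgb3, against 7.54. With the length correction it was 6.79 for Gpr179, and with the block added 6.71 for Gpr179 and 8.36 for H2-Oa. With limma-voom, Dusp27 (adjusted p = 0.18) and Gpr179 (adjusted p = 0.086) were no longer called.

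The 10 lower genes with the largest fitted folds under the naming rule were Rab33a, Hsd11b1, Dok5, Ankrd34b, Bex1, Gpr22, Crhbp, Fabp7, Tmem14a and Pvalb. Outside the rule, the lowest fitted log2 fold in the ependymal and choroid plexus list was -8.38. Rab33a, a small GTPase, had 1098 counts in input and 0 in IP, so it was at least 251-fold lower in IP. Hsd11b1, the enzyme that regenerates active glucocorticoid, fell from 28.8 ± 5.02 to 0.304 ± 0.301 CPM. Bex1 fell from 70.0 ± 16.8 to 1.95 ± 2.39 CPM, and Pvalb, the calcium-binding protein parvalbumin of inhibitory neurons, from 58.3 ± 6.41 to 1.95 ± 1.71 CPM. Crhbp, which binds corticotropin-releasing hormone, had a log2 fold of -5.05 (SE 0.71), and Fabp7, a fatty acid binding protein of astrocytes and progenitors, of -4.89 (SE 0.76). Without IP library 2 or pair 2 these were -6.09 and -6.27 for Crhbp and -5.98 and -5.97 for Fabp7, and that of Bex1, -5.21, was -7.02 and -6.81. Without IP library 1 or pair 1 the log2 fold of Hsd11b1, -6.38, was -7.68 and -7.58. With the length correction the log2 fold was -4.22 for Fabp7 and -4.50 for Bex1, and with limma-voom -6.13 for Bex1. That of Pvalb, -4.85, was -4.21 with the length correction and -5.99 with limma-voom.

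Markers of neurons, astrocytes and the oligodendrocyte lineage were lower in IP. All 15 pan-neuronal genes were lower, with a median log2 fold of -2.48 (camera adjusted p = 6.7e-14, and adjusted p = 0.018 with an estimated correlation). Snap25, a synaptic vesicle fusion protein, fell from 1955 ± 229 to 167 ± 19.7 CPM, and Eno2, neuronal enolase, from 1160 ± 25.7 to 188 ± 22.2 CPM. Of 15 markers of excitatory and hippocampal neurons, 10 were lower and none was called higher (camera adjusted p = 9.8e-06, and adjusted p = 0.22 with an estimated correlation). Adjusted over the list alone, 10 were lower and 1 was higher. Nrgn, a postsynaptic calmodulin-binding protein, fell from 3409 ± 463 to 302 ± 49.5 CPM. Camk2a, a calcium-dependent kinase of the synapse, was at 3103 ± 808 CPM in input and 2949 ± 1130 CPM in IP (log2 fold -0.07, SE 0.28, edgeR adjusted p = 0.86). Of 12 inhibitory neuron markers, 10 were lower, or 11 adjusted over the list alone, with a median of -2.66 (camera adjusted p = 5.9e-05, and adjusted p = 0.076 with an estimated correlation), or -3.48 without IP library 2. Sst, the peptide somatostatin, fell from 773 ± 31.9 to 27.8 ± 9.99 CPM, and Slc32a1, the vesicular GABA transporter, from 205 ± 106 to 21.1 ± 18.1 CPM (log2 fold -3.28, or -4.26 without IP library 2). With the length correction the log2 fold of Nrgn went from -3.50 to -2.90 and that of Sst from -4.80 to -4.01.

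Of 16 astrocyte markers, 15 were lower, with a median log2 fold of -2.31 (camera adjusted p = 3.2e-09, and adjusted p = 0.076 with an estimated correlation). Aldoc, an aldolase of astrocytes, fell from 1414 ± 113 to 132 ± 12.1 CPM, and Clu, clusterin, from 1201 ± 37.9 to 120 ± 30.9 CPM. The glutamate transporter Slc1a2 was not called (log2 fold -0.52, SE 0.28). All 16 oligodendrocyte markers were lower, with a median of -3.17 (camera adjusted p = 5.8e-07, and adjusted p = 0.22 with an estimated correlation). Mbp, myelin basic protein, fell from 3494 ± 1002 to 562 ± 161 CPM, and Mobp from 747 ± 151 to 187 ± 82.4 CPM. Of 10 tested markers of oligodendrocyte precursors, 6 were lower, among them Olig1 (log2 fold -3.14, SE 0.23) and Gpr17 (log2 fold -2.74, SE 0.28). The test of that list gave a camera adjusted p of 0.016, and an adjusted p = 0.13 with an estimated correlation.

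The fold of neuronal genes varied with the length of their transcripts. Over the 42 genes of the 3 neuronal lists, Spearman's rho between log2 fold and the length of the longest annotated transcript was 0.76, and Pearson's r with log2 length was 0.76. The permutation p was 1e-05 for both, the smallest that 100000 permutations give, with an adjusted p of 7e-05 over 7 gene classes. The rank correlation was 0.81, 0.68 and 0.62 in pairs 1, 2 and 3. Median log2 folds were -3.54, -2.35 and -1.39 in the shortest, middle and longest of 3 equal bins of these genes. The rank correlation was 0.65 for astrocyte markers (adjusted p = 0.017), 0.77 for precursor markers (adjusted p = 0.022) and 0.68 for endothelial markers (adjusted p = 0.017). It was 0.04 for oligodendrocyte (adjusted p = 0.87), 0.42 for mural (adjusted p = 0.18) and 0.27 for microglial and pan-myeloid genes (adjusted p = 0.15). These are relations across genes, which are not independent replicates, and differences between classes were not tested.

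**Figure D2:**
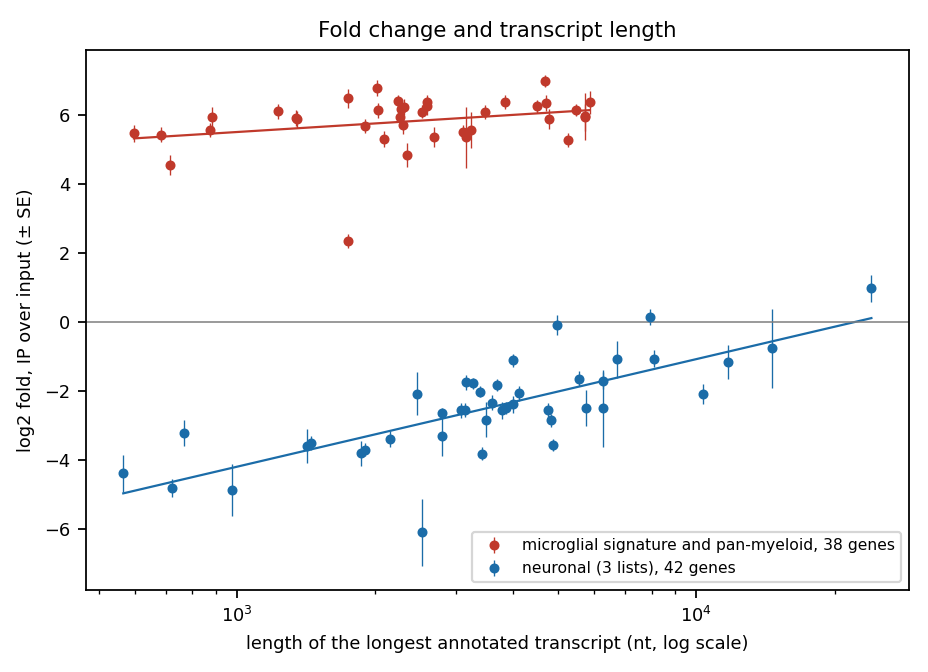
Fitted log2 fold of IP over input (y axis, bars are SE) against the length of the longest annotated transcript in nucleotides (x axis, log scale) for 42 neuronal and 38 microglial and pan-myeloid genes, with least-squares lines. The neuronal line rises by 0.94 on the log2 scale per doubling of length and the other by 0.25.

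Markers of the vessel wall and of blood did not move together. Of 15 endothelial markers, 8 were higher in IP, or 9 adjusted over the list alone, and none was lower. The median log2 fold was 2.53 (camera adjusted p = 0.026, and adjusted p = 0.56 with an estimated correlation). The camera adjusted p was 0.080 without IP library 3, with a median of 1.75, and 0.056 with DESeq2. The median was 3.29 with limma-voom and 3.24 with the block. Flt1, a receptor for vascular endothelial growth factor, rose from 1.94 ± 2.46 to 63.7 ± 25.0 CPM (log2 fold 5.04, or 6.92 without input library 3, 6.82 without pair 3, 4.35 without pair 1 and 5.81 with limma-voom), and Pecam1, an adhesion molecule of endothelium and blood cells, from 2.12 ± 1.16 to 61.8 ± 6.47 CPM. Of 13 tested mural cell markers, only Myh11, smooth muscle myosin, was called, and none adjusted over the list alone (list camera adjusted p = 0.82). Vtn was at 41.6 ± 11.6 CPM in input and 44.8 ± 32.4 CPM in IP, and Rgs5 at 23.9 ± 6.39 and 22.8 ± 17.5 CPM. The median of the mural list was 0.74, and its sign turned with limma-voom (-0.18) and with the block (-0.14). Of 9 tested fibroblast and meningeal markers, only Dcn, the matrix proteoglycan decorin, was called, at 31.7 ± 14.6 CPM in input and 5.16 ± 4.45 CPM in IP (list camera adjusted p = 0.89). The median of the list was 0.29 and its mean 0.34, while camera gave its direction as down. Without pair 1 the adjusted p of Dcn was 0.11, and its log2 fold of -2.62 was -3.53 without IP library 2 and -3.54 without pair 2. Igf2 was at 46.2 ± 36.2 and 50.1 ± 11.1 CPM.

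Of the 12 ependymal and choroid plexus markers 1 was lower, and none adjusted over the list alone, with a median log2 fold of -0.88 (list camera adjusted p = 0.44). The median was -1.49 without IP library 1 or IP library 2 and -1.50 with the block. The lower one, Tmem212, named after its values were seen, was at 2.19, 4.27 and 0.924 CPM in input libraries 1, 2 and 3 and at 0 in all 3 IP libraries. Ttr, transthyretin, the main secreted protein of the choroid plexus, was lower in both libraries of pair 3 than in the other pairs, at 3702, 2622 and 7.19 CPM in input libraries 1, 2 and 3 and at 561, 457 and 10.01 CPM in IP libraries 1, 2 and 3. It was not called (edgeR adjusted p = 0.37), and without pair 3 its log2 fold was -2.65 with an adjusted p of 0.00011. Kl, klotho, was at 43.3, 20.8 and 20.3 CPM in input libraries 1, 2 and 3 and at 36.1, 22.2 and 1.22 CPM in IP libraries 1, 2 and 3. Folr1, Clic6, Kcnj13 and Otx2, named after their values were seen, were at 0 to 0.770 CPM in both libraries of pair 3 and at 2.45 to 23.5 CPM in those of pairs 1 and 2.

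Of 8 tested erythroid and platelet markers, Gp9, a subunit of a platelet receptor, was higher at 36.2 ± 6.00 CPM from 0.0933 ± 0.162 CPM, with 6 counts in input library 1 and 0 in the other input libraries (log2 fold 8.42, or 7.78 without pair 2, 9.27 with limma-voom, 7.80 on thinned libraries, 7.39 with a prior count of 2 and 9.16 with the length correction), and Gp1bb, another subunit, was lower at 51.5 ± 9.65 CPM from 242 ± 12.1 CPM. These 2 subunits differed widely in input, and whether the counts of Gp1bb are of platelets was not tested. The list median was -2.04 (camera adjusted p = 0.52), or -3.30 with limma-voom, -3.53 with the block and -2.98 with the length correction and the block. Only 4 of 19 lymphocyte markers had enough counts to be tested. Of these, Ighm, the mu heavy chain, rose from 17.0 ± 1.33 to 488 ± 104 CPM. Cd79b had 3 counts in input and 428 in IP, a ratio of 210 (71.2 to 1020), or 117 without pair 3. The input counts of Cd79b were in library 1 alone. The lymphocyte list had a camera adjusted p of 0.038, an adjusted p = 0.17 with an estimated correlation and an adjusted p of 0.079 with the block. With no filter on low counts its median was -0.18, against 2.34, with an adjusted p of 0.17. Its call was also lost with limma-voom (0.21), on thinned libraries (0.0502), with the length correction (0.079, and 0.079 with the block added), and without input library 2 (0.052), input library 3 (0.059), IP library 2 (0.065), pair 2 (0.11) or pair 3 (0.056). Only 2 of 12 markers of border-associated macrophages had enough counts to be tested. Of these, Stab1, a scavenger receptor, was higher, at 455 ± 122 CPM from 5.77 ± 0.124 CPM. Mrc1 was at 0.347 ± 0.335 CPM in input and 1.69 ± 1.72 CPM in IP. Lcn2 and Mmp9, the only 2 of 16 monocyte and neutrophil markers with enough counts to be tested, were at 0.978 ± 1.06 and 0.761 ± 0.745 CPM in input. In IP they were at 1.33 ± 1.91 and 0.919 ± 1.59 CPM. Which cells the RNAs of Ighm, Cd79b and Stab1 come from was not tested.

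Among immune functions, complement, pattern recognition and antigen presentation genes were higher in IP. Of 15 tested complement genes, 8 were higher, with a median log2 fold of 1.87 (camera adjusted p = 5.5e-10, and adjusted p = 0.018 with an estimated correlation). The complement median was 5.64 with the stricter filter, 2.46 with the length correction and 2.47 with the block added. C1qa and C1qb, chains of the first complement component, reached 6871 ± 905 and 6817 ± 1314 CPM from 110 ± 10.2 and 95.9 ± 11.998 CPM. Their log2 folds went from 5.97 to 6.70 and from 6.15 to 6.85 with the length correction. C3 had a log2 fold of 0.38 with an SE of 1.91. Of 17 tested pattern recognition and inflammasome genes, 16 were higher, with a median of 5.50, or 4.74 without pair 1 (camera adjusted p = 2.2e-11, and adjusted p = 0.046 with an estimated correlation). Pycard, the inflammasome adaptor, rose from 4.01 ± 0.868 to 184 ± 51.5 CPM, and Cd14, a co-receptor for lipopolysaccharide, from 3.05 ± 1.48 to 170 ± 31.1 CPM (log2 fold 5.804, or 6.44 with the length correction and the block). Of 17 tested antigen presentation genes, 15 were higher, or 16 adjusted over the list alone, with a median of 3.95 (camera adjusted p = 1.3e-12, and adjusted p = 0.076 with an estimated correlation). B2m, the light chain of class I molecules, rose from 106 ± 17.1 to 1544 ± 227 CPM (log2 fold 3.87, or 4.67 with the length correction), and H2-D1 from 21.8 ± 0.897 to 338 ± 79.9 CPM. Of 11 tested cytokines and chemokines, 6 were higher, or 7 adjusted over the list alone, with a median of 4.69 (camera adjusted p = 5.9e-05, and adjusted p = 0.058 with an estimated correlation). Their median was 3.63 with no filter on low counts, 5.46 with the stricter filter, 5.43 with limma-voom, 5.44 with the block, 5.42 on thinned libraries and 5.78 with the length correction and the block. They included Tgfb1 (log2 fold 5.44, SE 0.20) and Ccl9 (log2 fold 5.55, SE 0.28).

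Of 18 tested interferon-stimulated genes, 9 were higher, with a median log2 fold of 2.13 (camera adjusted p = 0.026, and adjusted p = 0.22 with an estimated correlation). The list's adjusted p was 0.056 with DESeq2 and 0.071 with the length correction and the block. Bst2, tetherin, rose from 5.95 ± 1.35 to 58.1 ± 8.06 CPM (log2 fold 3.28, or 4.09 with the length correction). Of 21 tested disease-associated microglia genes, 12 were higher and 4 lower, with a median of 2.02 (camera adjusted p = 0.0027, and adjusted p = 0.22 with an estimated correlation). Ctsd, the lysosomal protease cathepsin D, rose from 556 ± 36.0 to 12853 ± 2771 CPM. The lower members were Apoe, Lpl, Fabp5 and Ank, and Apoe, a lipid carrier that astrocytes also make, fell from 3722 ± 517 to 1462 ± 286 CPM (log2 fold -1.35, or -0.73 with the length correction). Of 11 purinergic signalling genes, 7 were higher and Adora1 was lower, with a median of 4.14 (camera adjusted p = 1.6e-07, and adjusted p = 0.055 with an estimated correlation). The receptors P2ry12 and P2ry13 reached 813 ± 222 and 972 ± 121 CPM from 28.2 ± 12.7 and 14.1 ± 1.46 CPM. Of 23 lysosomal genes, 22 were higher, with a median of 3.15 (camera adjusted p = 2.7e-28, and adjusted p = 0.076 with an estimated correlation). Psap, prosaposin, rose from 1426 ± 73.8 to 3404 ± 756 CPM.

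Genes of the respiratory chain, glycolysis and cholesterol synthesis were mostly lower in IP. Of 20 nuclear-encoded respiratory chain genes, 19 were lower, or 20 adjusted over the list alone, with a median log2 fold of -1.47 (camera adjusted p = 5.2e-06, and adjusted p = 0.31 with an estimated correlation). That median was -0.81 with the length correction and -0.86 with the block added. Cox8a fell from 637 ± 78.4 to 163 ± 55.6 CPM and Cox4i1 from 593 ± 67.7 to 203 ± 14.3 CPM. Their log2 folds went from -1.97 to -1.10 and from -1.54 to -0.71 with the length correction. Of 8 tested mitochondrially encoded genes, 7 were lower, with a median of -2.38, or -3.05 without pair 1 (camera adjusted p = 0.0049, and adjusted p = 0.37 with an estimated correlation). mt-Co1 fell from 27244 ± 5391 to 2511 ± 1299 CPM, and mt-Cytb had a log2 fold of -3.43 (SE 0.39), or -2.80 with the length correction and -2.84 with the block added. The mitochondrial median was -3.09 with limma-voom, -3.08 with the block and -1.77 with the length correction. Of 14 glycolysis genes, 11 were lower, among them Aldoa (log2 fold -1.64, SE 0.16) and Pkm (log2 fold -0.76, SE 0.13), while the hexokinase Hk2 was higher (log2 fold 5.96, SE 0.25). The glycolysis list had a camera adjusted p of 0.034 and an adjusted p = 0.16 with an estimated correlation. Its call was also lost with the length correction (0.096, and 0.11 with the block added) and without IP library 1 (0.058), IP library 2 (0.052), pair 1 (0.069) or pair 2 (0.069). Of 11 tested cholesterol synthesis genes, 9 were lower, or 10 adjusted over the list alone, with a median of -1.29 (camera adjusted p = 0.0054, and adjusted p = 0.13 with an estimated correlation). Srebf2, the regulator of the pathway, fell from 242 ± 32.8 to 112 ± 10.1 CPM and Hmgcs1 from 105 ± 16.9 to 42.8 ± 8.11 CPM.

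Of 15 immediate early genes, 3 were higher and 7 lower, with a median log2 fold of -1.39, or -0.50 without pair 3 (camera adjusted p = 0.28). Egr1 fell from 339 ± 103 to 43.8 ± 18.9 CPM, and Junb was at 163 ± 46.4 and 158 ± 12.8 CPM. Of 11 tested cell cycle genes, 4 were higher, with a median of 1.63 (camera adjusted p = 0.17, and adjusted p = 0.028 with limma-voom). Mcm3, a subunit of the replicative helicase, had a log2 fold of 4.13 (SE 0.53), and Pcna of 0.78 (SE 0.33, edgeR adjusted p = 0.079). Pcna was called higher with limma-voom (adjusted p = 0.031), with the length correction (0.0062, and 0.0036 with the block added), and without input library 1 (0.048) or IP library 3 (0.029). Of 50 tested cytosolic ribosomal protein genes, 2 were higher and 6 lower, or 1 and 5 adjusted over the list alone (camera adjusted p = 0.28). The median of this list was -0.33 and turned to 0.29 with a correction for transcript length. Rpl4 was at 452 ± 36.1 CPM in input and 466 ± 42.0 CPM in IP, and Rpl8 at 429 ± 98.3 and 440 ± 48.8 CPM. Rpl22, the gene that carries the tag (ENSMUSG00000028936, chromosome 4, 152325742 to 152334071, plus strand), was at 66.1 ± 3.04 and 69.6 ± 13.3 CPM, with a log2 fold of 0.07 and an SE of 0.19. The sign for Rpl4, Rpl8 and Rpl22 turned with upper quartile factors and with library totals. With the length correction, these 3 genes were called higher.

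Of 8 tested nuclear non-coding RNAs, 7 were higher in IP and Rian was lower, with a median log2 fold of 2.004 (camera adjusted p = 0.00064, and adjusted p = 0.16 with an estimated correlation). Meg3 rose from 240 ± 32.9 to 1515 ± 130 CPM and Snhg11 from 151 ± 19.1 to 574 ± 74.5 CPM. The list holds Snhg11 as non-coding, while GENCODE M21 gives its type as protein-coding. Xist, the RNA that coats the inactive X chromosome, rose from 14.1 ± 5.90 to 302 ± 66.6 CPM. The log2 fold of Xist went from 4.42 to 3.32 and that of Meg3 from 2.66 to 1.66 with the length correction. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in all 6 libraries, beside labels that give the mice as female.

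Kdm6a, the histone demethylase of the series title (ENSMUSG00000037369, chromosome X, 18162575 to 18279936, plus strand), was detected in all 6 libraries at low abundance. It was at 7.71 ± 1.28 CPM in input and 10.7 ± 4.30 CPM in IP (log2 fold 0.47, SE 0.46, edgeR adjusted p = 0.44). Of the 16 enzymes of H3K27 and H3K4 methylation, 11 were higher in IP, with a median of 1.54 (camera adjusted p = 0.00013, and adjusted p = 0.16 with an estimated correlation). Kmt2d, a histone methyltransferase, rose from 37.5 ± 9.40 to 276 ± 46.8 CPM (log2 fold 2.88, or 1.68 with the length correction), and Kdm5c from 41.1 ± 5.27 to 169 ± 7.01 CPM. Of 5 genes that escape X inactivation, Kdm5c and Ddx3x were higher (list median 0.47, camera adjusted p = 0.24), and Ddx3x was at 91.7 ± 24.3 CPM in input and 189 ± 24.3 CPM in IP.

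**Figure D3:**
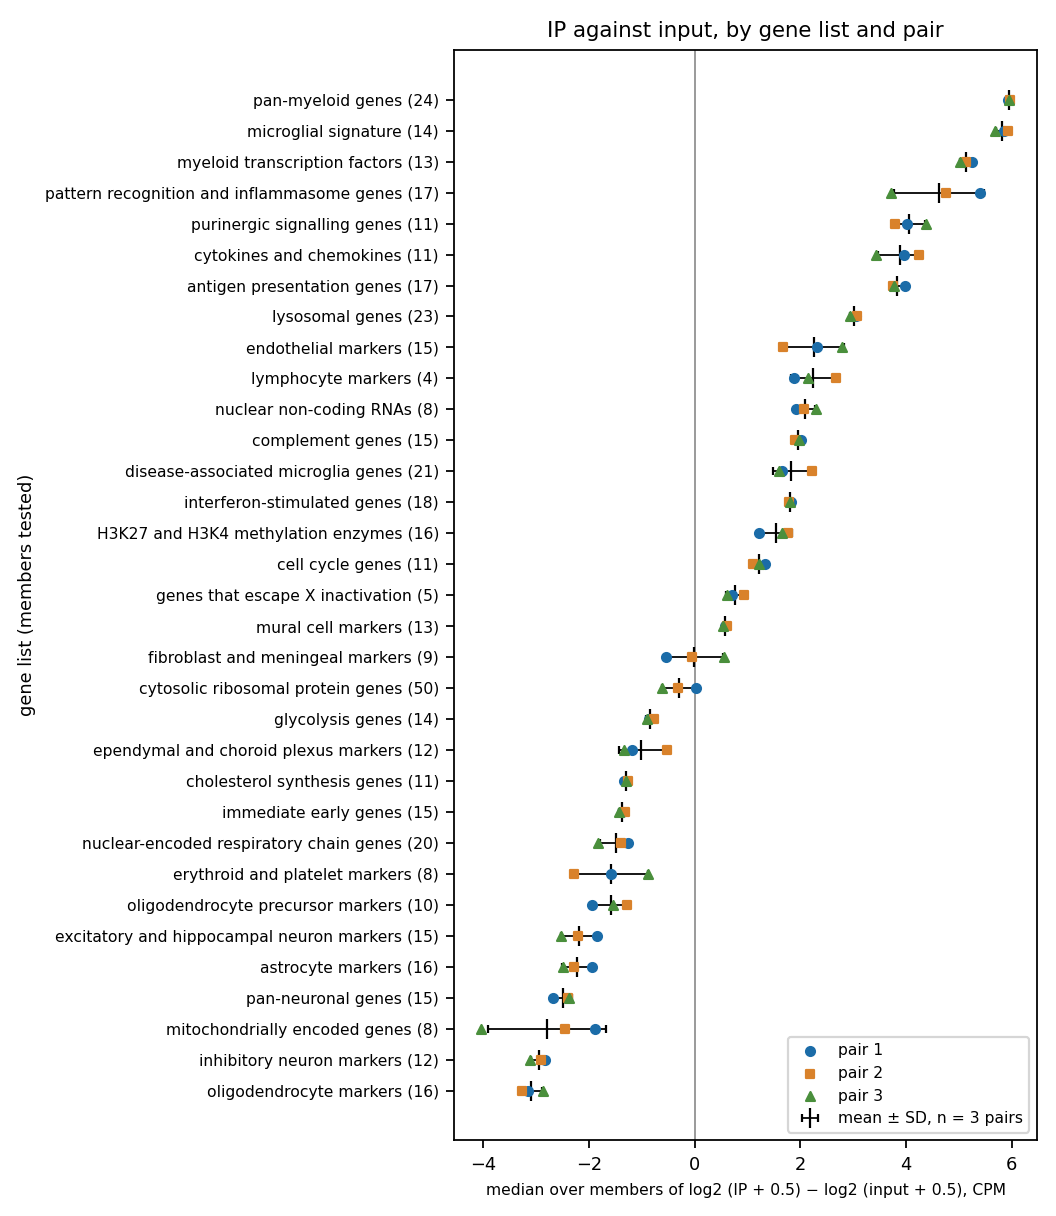
Median over list members of the log2 difference of IP and input (CPM + 0.5) in each of 3 pairs (points), with the mean and SD of the pairs (bars), for 33 gene lists. Pan-myeloid genes lie at 5.94 ± 0.03 and oligodendrocyte markers at -3.09 ± 0.21, and mitochondrially encoded genes have the widest spread, at -2.79 ± 1.12.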

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

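The transcript length correction was chosen after seeing the data, and all other settings were planned. The microglial signature median stayed between 5.64 and 6.16 and its list test stayed called under each setting that changed 1 choice, but not with the block and an estimated correlation together (adjusted p = 0.12). Genes higher in IP ranged from 2802 to 3888 and genes lower in IP from 2526 to 4189 when libraries or pairs were left out. The lowest counts, 2802 and 2526, were without pair 1, and without pair 2 they were 2930 and 2917. A 2-fold minimum gave 2176 higher and 2020 lower genes, by a stricter hypothesis. The title code as a replicate block gave 3698 higher and 3784 lower genes, a signature median of 5.87 and 24 called lists. It ended the call of the lymphocyte list (0.079), of no other list and of no named gene, and it moved no count of genes by over 1.5 times. Camera called 25 lists with the preset correlation and 6 with an estimated one. The estimate was -0.064 for complement, -0.010 for precursor and -0.013 for glycolysis genes, all under the preset 0.01. Their camera adjusted p still rose, for complement from 5.5e-10 to 0.018. The versions of camera therefore differ in more than the correlation, and lost calls cannot be laid to correlation alone. With the block and an estimated correlation together none was called, the smallest adjusted p being 0.12. Fry called 28 lists, or 29 with the block. The per-pair signature median was 5.82 and moved to 5.61 with a pseudocount of 2 CPM, since a larger pseudocount shrinks folds of rare genes. The median of all genes moved by -0.13 with upper quartile factors, -0.10 with library totals, -0.13 with limma-voom, -0.12 with the block and 0.19 with the length correction. The higher genes were 44.9% to 55.2% of the calls, against 49.9%. The length correction gave 4227 higher and 3436 lower genes, or 3968 and 3375 with the block. Of the 7722 calls, 6748 were called again after that correction and 6747 of these had the same direction.

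Changes of sign were among genes and lists near 0 or with few counts. The median of all genes moved by -0.13 with upper quartile factors and by -0.10 with library totals. The genes that turned had main log2 folds of 0.036 to 0.12 in the first case and 0.036 to 0.075 in the second. These are smaller than the shift, which by itself can turn them. The cause of the other changes of sign was not tested. With upper quartile factors, Vtn was at -0.014, Igf2 at -0.011, Rpl4 at -0.086, Rpl8 at -0.093 and Rpl22 at -0.049. With library totals, Rpl4 was at -0.062, Rpl8 at -0.068 and Rpl22 at -0.020. Without a low-count filter, the lymphocyte list was at -0.18. With limma-voom, the mural list was at -0.18, Mmp9 at -0.67 and Vtn at -0.31. With the replicate block, the mural list and Vtn were at -0.14 and Mmp9 at -1.24. With the length correction, the ribosomal protein list was at 0.29 and Junb at 0.48, and with the block added they were at 0.23 and 0.51 and Mmp9 at -1.05. Junb was then called (adjusted p = 0.019; 0.11 without the block). When libraries or pairs were left out, Camk2a ranged from -0.42 to 0.13, Igf2 from -0.35 to 0.89, Junb from -0.23 to 0.20, Kl from -1.26 to 0.055, Lcn2 from -2.05 to 1.66, Mmp9 from -6.66 to 1.77, Rgs5 from -0.92 to 0.35, Rpl22 from -0.092 to 0.19, Rpl4 from -0.039 to 0.099, Rpl8 from -0.11 to 0.23, Vtn from -0.61 to 0.51 and the fibroblast list from -0.0050 to 0.66. Linear folds of 20 called named genes moved by over 1.5 times with the length correction, 18 with the block added, 9 with limma-voom and 8 with a prior count of 2. With libraries thinned to the smallest total, 3893 genes were higher and 3790 lower.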

Other observations

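The tests on GC content, on the slope with a term for dendritic mRNAs, on non-coding RNAs as microglial RNA, and on endothelial markers were chosen after the result was seen. The tests on the length trend in microglial genes, on the residual of dendritic mRNAs and on the length trend of the 5 non-coding RNAs together were written before it. The genes in the next 3 sentences were chosen after their values were seen. Trp53bp1, a DNA damage response protein (chromosome 2, 121193281 to 121271407, minus strand), was at 67.1 ± 1.97 CPM in input and 10342 ± 2790 CPM in IP, where it ranked 4 of all tested genes by abundance, against 2988 in input. Tubgcp4, which overlaps it on the other strand from 121193281 to 121198770, was at 26.5 ± 1.87 and 965 ± 274 CPM, and Bcar1, an adaptor of focal adhesions (chromosome 8, 111710474 to 111743809), at 97.9 ± 12.9 and 8152 ± 2206 CPM. Gm42418, a gene model that took 0.0855% to 0.0983% of the counts in input, took 1.89% to 2.58% in IP, and Lars2 was at 61.0 ± 24.8 and 1792 ± 390 CPM. Whether the counts of Trp53bp1, Tubgcp4, Bcar1, Gm42418 and Lars2 in IP are of their mRNA, of ribosomal RNA or of another origin was not settled, since read coverage was not analysed here.

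Long neuronal transcripts were less depleted in IP than short ones, with a slope of 0.94 on the log2 scale per doubling of length, and slopes were 0.96 for astrocyte, 0.94 for precursor, 1.16 for endothelial, 0.92 (95% interval -0.049 to 1.74) for mural and -0.12 (-1.60 to 0.79) for oligodendrocyte markers. Over all protein-coding genes the median log2 fold was -0.71 in the shortest and 0.60 in the longest of 10 nearly equal bins by length, so a length trend shared by RNAs of several cell types stays open, but one of the neuronal size in all RNAs is argued against by the microglial and pan-myeloid genes, whose slope was 0.25 (0.06 to 0.45), the upper bound lying only just under 0.47, the limit set beforehand as a fraction of the neuronal slope. GC content is argued against as the whole cause, since its rho with the fold over the 42 neuronal genes was 0.023 (-0.31 to 0.35). A list of 19 mRNAs chosen from background knowledge as dendritic or synaptic, 4 higher and 9 lower with a median log2 fold of -0.67, lay above the neuronal length line by a median of 1.48 (0.772 to 2.173; a first run that had left out 4 planned members by mistake gave 1.53), but such a residual has length taken out, and the slope was 0.97 with a term for this list. Location in dendrites stays open as a cause of the trend, since the neuronal lists also hold dendritic mRNAs, and expression of such genes in microglia, and lengths that differ from the expressed isoform, were not tested and stay open.

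Of the list of nuclear non-coding RNAs, 5 are known as enriched in neurons: Meg3, Rian, Mirg, Miat and Snhg11. The first 3 come from 1 imprinted locus and are not independent, and GENCODE M21 gives the type of Snhg11 as protein-coding. The 5 lay above the neuronal length line by a median of 3.27. By the limit set beforehand for the median, this counts against the length trend of neuronal mRNAs. Their range of 0.54, for Rian, to 4.28 still reached within 1 residual SD, 0.90, of the line. For the 5 as a set the trend is therefore left open, a more cautious reading than that limit. Nuclear RNA of microglia alone stays open: the median log2 fold of the 5 was 1.92, with members from -0.81 to 2.66, and how much of each microglia express was not measured here. Recovery of nuclear RNA from lysed neurons may also account for them, but no library of beads without tagged ribosomes was analysed here. Malat1, Xist and Neat1, which microglia also express, cannot be assigned to a cell type.

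Endothelial markers lay above the neuronal length line by a median of 5.13 (4.77 to 6.61). They were thus not depleted as neuronal mRNAs of like length were. Both folds were known when the test was chosen, so it restates them and is no separate test of background as a cause. Carry-over of whole vessel fragments, with endothelial and mural cells alike, stays open. Mural markers lay above the line by less than endothelial markers, the difference of medians being 1.59 (permutation p = 0.014, two-sided). The permutation takes marker genes as independent, the folds were known beforehand, and mural markers also lay above the line. Ribosome tagging in endothelial cells cannot be told apart from other routes: all 15 markers lay above the line by more than 1 residual SD, but so did the mural markers by a median of 3.53, and no library from mice without Cre was analysed here. Expression of some of these markers in microglia may also contribute and was not tested.

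The 6 libraries can be split into 2 groups of 3 in 10 ways, which are too few for a share under 0.05. The real split gave 3853 higher and 3869 lower genes with edgeR, and the other 9 gave at most 0 in either direction, with at most 67 at an unadjusted p under 0.05. Each of the other 9 mixes IP and input libraries in both parts, so the large IP and input differences widen the spread within parts. Few calls were therefore bound to follow in them, and their counts lend the real split no support. In 1 of 10 splits, the real one, as many genes were called, for higher and for lower genes alike. Of the 10, 4 part all 3 pairs, the real one included, and the other 6 part 1 pair. No other tool was run on the splits.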
